A study of Mus musculus with 21 samples.

How the data were processed

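RNA was measured in mouse embryonic fibroblasts (MEFs) with and without thapsigargin, in whole lysates and in 3 pools of a sucrose gradient, on 21 Affymetrix arrays of the 3' in vitro transcription type. Per the labels' protocols, 14 gradient fractions were merged into pools of fractions 1 to 4, 5 to 8 and 9 to 14. Synthetic luciferase RNA and bacterial poly-A spike-in RNAs were added to each pool before RNA was purified, with later normalization as the stated purpose, and 2 ug of RNA was labelled for every array. Gradient samples, treated or not, also received 50 ug/mL cycloheximide, which holds ribosomes on mRNA, for 10 min.

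The deposited values were log2 signals, as their steps and range show; the authors' scale and scaling are not given in the sources used here. MAS5 and GCOS, the array maker's signal algorithm and software, are named in the submitters' processing notes, with no version. The mean of the 12 poly-A spike-in probe sets stayed between 10.21 and 10.91 log2 units on all arrays, while array medians ran from 7.095 to 12.13, so the values look scaled per array to the spike-ins. That reading rests on the values alone, and whether the scaling makes absolute amounts comparable between pools stays unknown. The table held 45101 probe sets and 38 missing values, none of them in a tested gene.

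Gene symbols came from the platform annotation supplied with the table. Exactly 1 symbol was listed for 34958 probe sets, several for 932 and none for 9211. The Entrez identifiers of 34741 of the 34945 usable probe sets were found in a mouse gene table of assembly GRCm38.p6, which changed 0 symbols and also supplied each gene's biotype and length. The 64 control probe sets and those without exactly 1 symbol were left out, then the 40% of the others with the lowest mean over all arrays. This left 20967 probe sets, and each of the 11270 genes was represented by its probe set with the highest mean. Gapdh could not be tested, since the 3 probe sets that list it outside the controls also list other symbols.

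Each array was centred on its median over the kept probe sets, so every change is relative to the median probe set of the same array and not an absolute amount. Changes were tested with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes with a mean trend), with Benjamini-Hochberg adjustment over the 11270 genes and a threshold of 0.05. Every adjusted p printed for a gene is limma's. Total RNA was fitted on its own 6 arrays, and the gradient comparisons on the 15 gradient arrays in 1 model with 6 groups, because 2 thapsigargin gradients alone leave too few degrees of freedom. No term for culture was in the main fits, so pools of 1 gradient were treated as independent. Deviations of the control pools of 1 culture correlated at -0.03 to 0.09. The gradient comparisons were thapsigargin against control within each pool, polysome against free pool in control cells, and the interaction of treatment with polysome minus free, called the polysome shift. The change on polysomes beyond that in total RNA was an interaction in a model of all 21 arrays. Thapsigargin gradient replicate 1 was not analysed here. The replicates are biological ones per the labels, and the number of arrays limits the precision.

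Before the data were examined, 27 gene lists were fixed, and 22 of them had at least 5 tested genes. They covered the integrated stress response, tRNA synthetases, ER chaperones, ER-associated degradation, ER translocation, mRNAs with upstream reading frames, ribosomal proteins, other 5' TOP mRNAs, sterol synthesis, the cell cycle, extracellular matrix, nuclear and mitochondrial genes of respiration, the proteasome, NF-kappaB targets, immediate early genes, apoptosis, autophagy, the eIF2 machinery, substrates of IRE1-dependent decay, and markers of fibroblasts, macrophages, endothelium, epithelium, muscle, fat and nerve. Lists were tested with camera at a preset correlation of 0.01, adjusted over 154 list-by-comparison tests. Of 61 calls, 17 also passed with an estimated correlation. The fry test, which asks whether a list's genes move on balance in a single direction without comparing them with other genes, called 95. Where a list's test is given, its count adjusted over the list alone stands beside the count over all genes.

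The genes named in the text follow a rule written in advance. It takes, per comparison, the 8 largest called rises and the 8 largest called falls whose samples do not overlap, up to 4 called members of each list with the largest change, and 11 genes whatever their values: Atf4, Atf5, Ddit3, Ppp1r15a, Ppp1r15b, Ibtk, Eprs, Slc35a4, Hspa5, Actb and Gapdh. For the shift, the values that could not overlap were polysome minus free per culture. For the change beyond total RNA they were the polysome values alone, which can lie apart in either direction. Clone and predicted genes could be passed over, and the text does not name every gene the rule yields. Where a named gene's mean in a group of the comparison lay among the dimmest 40% of usable probe sets in that group, the text calls the signal dim and gives no change, a limit set after the values were seen. The share of a transcript's signal in the polysome pool was the deposited polysome signal, on a linear scale, divided by the sum of free, light and polysome signals of the same culture. It was given without a p, because 3 against 2 cultures cannot reach an exact p below 0.1, and that bound is a property of the design.

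The fits were tested on simulated data with 200 changed genes among 11270 before use. At a log2 change of 1, the total RNA fit recovered 55% of the changed genes, the polysome pool 72%, the light pool 68%, the free pool 70%, control polysome against free 73%, the polysome shift 47% and the change beyond total RNA 56%. At a log2 change of 2 these were 91%, 95%, 95%, 97%, 97%, 85% and 91%, with between 3 and 8 unchanged genes called. The simulated noise was normal, independent between genes and of equal spread on every array. These figures therefore do not cover correlated genes, arrays that stand apart or changes in many more genes. Alternatives covered the scaling of arrays, the filter, the probe set per gene, array weights, the arrays in the model, a size threshold, a block for the replicate, the mark "(2)" in some array names, and leaving out each replicate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.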

Results

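The study examined mouse embryonic fibroblasts (MEFs), connective tissue cells cultured from C57BL/6 embryos, that were left untreated or given 1 uM thapsigargin for 6 h. Thapsigargin blocks the calcium pump of the endoplasmic reticulum (ER), which disturbs protein folding there and leads to phosphorylation of the translation factor eIF2. The design asks which mRNAs change in amount under ER stress and which change in their load of ribosomes. Total RNA was measured in 3 control and 3 thapsigargin samples. Gradients of 3 control and 2 thapsigargin cultures each gave a free pool from the top of the gradient, a light pool with 1 to 3 ribosomes per mRNA and a polysome pool with at least 4. Arrays of 1 group correlated at 0.955 to 0.989 across genes. Thapsigargin total RNA array 2 stood apart by its 18S ribosomal RNA signal, 2.48 log2 units above the array median against at most -0.61 in control total RNA. Thapsigargin free array 3 had a signal for the 3' end of the dap spike-in 3.62 log2 units above that for the 5' end, against at most 0.44 on control free arrays and 2.36 to 3.57 on the total RNA arrays.

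In total RNA, thapsigargin raised 27 of 30 transcripts of the integrated stress response (ISR), the program that follows eIF2 phosphorylation, and 18 of 25 of ER protein folding. Ddit3, which encodes the transcription factor CHOP, rose 20.8-fold (log2 4.38 ± 0.13 SE, n = 3 and 3, adjusted p = 1.64e-08 by limma), with a second probe set at a log2 of 3.71. Trib3, a pseudokinase induced by CHOP, rose 11.3-fold, and Herpud1, an ER membrane protein of the degradation machinery, 10.5-fold. Thbs1, which encodes the matrix protein thrombospondin 1, fell 15.1-fold (log2 -3.92 ± 0.19 SE, adjusted p = 5.6e-07). Islr and Edn1, the precursor of the vasoconstrictor endothelin 1, fell to a dim signal, for which no fold is given.

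Of the 30 measured ISR genes, 27 rose and 3 were not called, and 28 rose when adjusted over the list alone (camera adjusted p = 3.1e-30, and adjusted p = 0.0987 with an estimated correlation). Atf3 rose 7.28-fold and Ppp1r15a, which encodes the GADD34 subunit that directs dephosphorylation of eIF2, 6.39-fold. Of 25 ER chaperones and folding enzymes, 18 rose and 7 were not called, with 20 rises adjusted over the list alone (camera adjusted p = 6.36e-19; adjusted p = 0.0305 with an estimated correlation). Among them Sdf2l1 rose 9.59-fold, the oxidase gene Ero1b 6.33-fold, Dnajc3 5.52-fold and Creld2 5.4-fold. Hspa5, which encodes the chief ER chaperone BiP, rose 2.05-fold (log2 1.04 ± 0.11 SE). In ER-associated degradation, 9 of 18 genes rose and 9 were not called, 9 rising and 1 falling when adjusted over the list alone, with Sel1l up 5.9-fold and Syvn1, a ubiquitin ligase, up 4.97-fold (camera adjusted p = 1.31e-08; adjusted p = 0.0653 with an estimated correlation). Of 19 aminoacyl-tRNA synthetases, which load tRNAs with amino acids, 12 rose, 13 adjusted over the list alone, with Wars up 3.37-fold and Tars 1.89-fold (camera adjusted p = 3.19e-09; adjusted p = 0.257 with an estimated correlation). In ER translocation 9 of 22 genes rose, 11 adjusted over the list alone, with Sec11c of the signal peptidase up 2.37-fold (camera adjusted p = 0.00016; adjusted p = 0.178 with an estimated correlation).

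Of 15 mRNAs with upstream open reading frames described as preferentially translated when eIF2 is phosphorylated, 9 rose, 2 fell and 4 were not called, with 10 rises and 2 falls adjusted over the list alone (camera adjusted p = 9.07e-07; adjusted p = 0.171 with an estimated correlation). The study picked Ibtk on these samples, and possibly Eprs, so this list is not independent evidence of its direction here or in any later comparison. Atf4, the main transcription factor of the ISR, rose 1.53-fold (log2 0.62 ± 0.12 SE, adjusted p = 0.00624, a second probe set at 1.17) and Atf5 2.76-fold. Ibtk, an inhibitor of Bruton's tyrosine kinase, rose 3.12-fold, Cebpb 3.49-fold and Eprs, the glutamyl-prolyl-tRNA synthetase, 1.67-fold. Slc35a4 fell 1.47-fold, and Ppp1r15b, which encodes the constitutive CReP partner of eIF2 phosphatase, was not called (log2 0.15 ± 0.17 SE). Actb was not called either (log2 -0.18 ± 0.10 SE, adjusted p = 0.284), and a second Actb probe set gave 0.45. The metallothionein gene Mt2 rose 6.75-fold and Acot2 6.72-fold, and Car6 rose from a dim signal.

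Of 26 collagen and matrix genes, 14 fell, 1 rose and 11 were not called, with 19 falls adjusted over the list alone (camera adjusted p = 3.91e-09; adjusted p = 0.298 with an estimated correlation). Col3a1 fell 7-fold, the proteoglycan gene Dcn 3.8-fold, and, outside the list, Nrep 10.9-fold and Tgfbi 9.82-fold. Of 10 fibroblast markers, some shared with the matrix list, 5 fell and 5 were not called, 6 falling when adjusted over the list alone (camera adjusted p = 0.000888; adjusted p = 0.331 with an estimated correlation). Of 7 substrates of decay by the ER nuclease IRE1, 6 fell over all genes and over the list alone, Scara3 by 5.62-fold and Pdgfrb by 2.76-fold (camera adjusted p = 5.15e-07; adjusted p = 0.171 with an estimated correlation). In sterol synthesis 7 of 19 genes fell, also when adjusted over the list alone, with Hmgcs1 down 2.77-fold and Idi1 1.92-fold (camera adjusted p = 0.000353; adjusted p = 0.171 with an estimated correlation). Of 72 nuclear genes of oxidative phosphorylation, 10 fell and 62 were not called, 10 also over the list alone, with Uqcrh down 2.07-fold and Ndufb3 1.83-fold (camera adjusted p = 0.00118; adjusted p = 0.8 with an estimated correlation). Of 42 ribosomal protein genes, 41 were not called and Rps27 rose 2.22-fold, a rise that was not called over the list alone.

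In total, 821 genes rose and 880 fell among 11270 (1701 calls), of which 190 and 365 changed by a log2 of at least 1. Without centring, 470 rose and 870 fell. Without thapsigargin array 2, the array with the high 18S signal, there were 3327 calls, with 28 rises in the ISR list, 21 among ER chaperones and 21 falls in the matrix list. Of 72 oxidative phosphorylation genes 30 then fell and 0 rose. In sterol synthesis 10 of 19 fell and 1 rose, and of 42 ribosomal protein genes 5 fell and 1 rose. Without thapsigargin array 3 there were 979, and without control array 1, 2 or 3 there were 876, 812 and 890.

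On polysomes, 25 of 30 ISR genes and 20 of 25 ER chaperones rose. Ddit3 rose 29.3-fold (log2 4.87 ± 0.15 SE, n = 2 and 3, adjusted p = 5.67e-12), with the second probe set at a log2 of 3.18. Herpud1 rose 9.6-fold, Sdf2l1 9.51-fold, Trib3 9.12-fold and the disulfide isomerase gene Pdia4 8.85-fold. Nrep fell 16.7-fold and Adm, the precursor of the peptide hormone adrenomedullin, 11.4-fold, and the growth factor gene Fgf5 and Islr fell to a dim signal. Of 72 genes of respiration 48 fell, and of 30 cell cycle and DNA replication genes 14 rose and 5 fell.

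Of 30 ISR genes on polysomes, 25 rose and 5 were not called, with 27 rises adjusted over the list alone (camera adjusted p = 7.79e-23; adjusted p = 0.00407 with an estimated correlation). They included Aldh1l2, an enzyme of mitochondrial folate metabolism (6.49-fold), and Atf3 (6.46-fold). Of 25 ER chaperones 20 rose and 1 fell, the same numbers over the list alone (camera adjusted p = 1.88e-13; adjusted p = 0.00268 with an estimated correlation), with Dnajc3 up 4.29-fold and Hspa5 2.14-fold. In ER-associated degradation 11 of 18 rose and 1 fell, with the same numbers adjusted over the list alone and Sel1l up 6-fold (camera adjusted p = 3.32e-06; adjusted p = 0.00741 with an estimated correlation). Of 19 synthetases 15 rose and 4 were not called, 16 rising when adjusted over the list alone, with Eprs up 4.66-fold (log2 2.22 ± 0.10 SE), Wars 3.44-fold, Tars 3.41-fold and Aars 3.22-fold (camera adjusted p = 1.86e-12; adjusted p = 0.014 with an estimated correlation). In ER translocation 7 of 22 rose and 1 fell, 8 and 2 over the list alone (camera adjusted p = 0.0329; adjusted p = 0.303 with an estimated correlation).

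Among the 15 mRNAs with upstream reading frames, 8 rose and 2 fell on polysomes, with the same numbers adjusted over the list alone (camera adjusted p = 3.73e-06; adjusted p = 0.00866 with an estimated correlation). Ppp1r15a rose 6.12-fold, Ibtk 4.85-fold (log2 2.28 ± 0.16 SE), Atf5 3.43-fold and Atf4 2.13-fold (log2 1.09 ± 0.11 SE). Slc35a4 fell 1.45-fold, while Ppp1r15b (log2 0.09 ± 0.09 SE) and Actb (log2 -0.22 ± 0.13 SE, a second probe set at 0.86) were not called.

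Of 30 cell cycle and DNA replication genes, 14 rose and 5 fell on polysomes, 15 and 6 over the list alone (camera adjusted p = 0.00551; adjusted p = 0.164 with an estimated correlation). Cdc6, which loads the replicative helicase, rose 2.82-fold, the helicase subunit Mcm4 2.24-fold, the mitotic kinesin Kif11 2.09-fold and the topoisomerase Top2a 2.06-fold. Of 72 oxidative phosphorylation genes, 48 fell and 2 rose, with 51 and 2 over the list alone (camera adjusted p = 5.99e-07; adjusted p = 0.441 with an estimated correlation), among them Uqcrh (2.67-fold lower), Ndufb3 (2.28-fold) and Ndufb10 (1.78-fold). Of 42 ribosomal protein genes 12 fell and 1 rose, 11 and 1 over the list alone (camera adjusted p = 0.0092; adjusted p = 0.757 with an estimated correlation). Rps25 fell 2.06-fold and Rpl14 1.44-fold, but the list's median lay -0.12 from that of all genes and at 0.03 with quantile normalization. Of 34 proteasome genes 12 fell and 2 rose, 16 and 2 over the list alone, Psmd1 rising 1.87-fold (camera adjusted p = 0.0491; adjusted p = 0.449 with an estimated correlation). In sterol synthesis 11 of 19 fell and 1 rose, also over the list alone, Hmgcs1 by 1.76-fold and Idi1 by 1.69-fold (camera adjusted p = 0.0142; adjusted p = 0.209 with an estimated correlation). Among 26 matrix genes 11 fell and 7 rose, also over the list alone, with no call for the list (camera adjusted p = 0.49), and with Thbs1 down 11.7-fold, Dcn 4.79-fold and Col3a1 2.76-fold. Of 7 IRE1 decay substrates 5 fell, also over the list alone, Scara3 by 8.24-fold (camera adjusted p = 0.000759; adjusted p = 0.118 with an estimated correlation).

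Together 1833 genes rose and 2780 fell on polysomes (4613 calls). The median change of all genes was -0.11 after centring and 0.09 as deposited, where 1801 rose and 808 fell, and scaling to the spike-ins gave 872 and 380. Total RNA and polysome pools share no arrays, but their labels carry the same replicate numbers, so they may come from the same cultures. Of the 821 genes higher in total RNA, 583 were also higher on polysomes, against 133.5 for independent lists, and of 880 lower genes 765 were also lower, against 217.1. Without thapsigargin polysome replicate 2 there were 3024 calls.

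**Figure D1:**
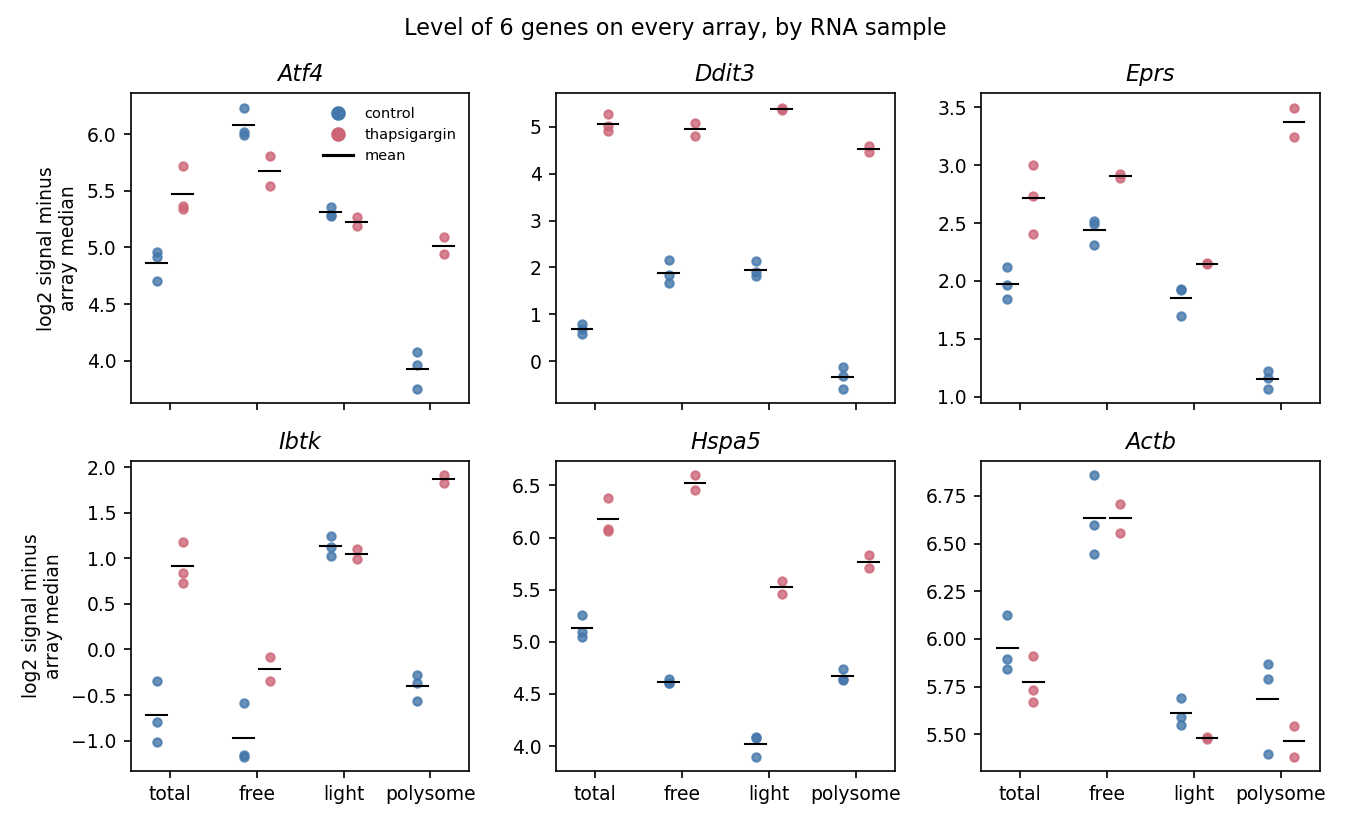
Level of 6 genes on every array, as log2 signal minus the array median (vertical axis), in total RNA and the 3 gradient pools (horizontal axis); points are arrays, blue for control (n = 3) and red for thapsigargin (n = 3 in total RNA, 2 in the pools), and black lines are means. Polysome levels of Ibtk and Eprs under thapsigargin lie above all control polysome values, while Actb was called in none of the 4 comparisons with thapsigargin shown.

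In the light pool, where mRNAs carry 1 to 3 ribosomes, 24 of 25 ER folding genes and 24 of 34 proteasome genes rose, and 19 of 26 matrix genes fell. Creld2 rose 12.1-fold (log2 3.60 ± 0.11 SE, n = 2 and 3, adjusted p = 2.96e-12), Dnajc3 7.33-fold and Hspa5 2.84-fold. Psma6, Psmc5, Psmd6 and Psma1, subunits of the proteasome, rose 2.15-, 2.11-, 2- and 1.92-fold. Tgfbi fell 15-fold and Col3a1 5.41-fold, and Thbs1 fell to a dim signal. Eprs rose 1.23-fold, and neither Atf4 (log2 -0.08 ± 0.11 SE) nor Ibtk (log2 -0.09 ± 0.16 SE) was called.

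Of 25 ER chaperones 24 rose in the light pool, also over the list alone (camera adjusted p = 7.04e-20; adjusted p = 0.000761 with an estimated correlation), and of 34 proteasome genes 24 rose and 1 fell, 25 and 1 over the list alone (camera adjusted p = 5.44e-07; adjusted p = 0.0875 with an estimated correlation). In the ISR list 25 of 30 rose, 26 over the list alone with 1 fall, Trib3 by 10.9-fold and Ddit3 by 10.8-fold (camera adjusted p = 3.52e-18; adjusted p = 0.00657 with an estimated correlation). In ER-associated degradation 12 of 18 rose and 1 fell, 13 and 1 over the list alone, Herpud1 by 14-fold (camera adjusted p = 3.98e-07; adjusted p = 0.00528 with an estimated correlation). In ER translocation 13 of 22 rose, also over the list alone, including Srprb (3.1-fold) and Sec11c (2.44-fold) (camera adjusted p = 3.28e-05; adjusted p = 0.0838 with an estimated correlation). Of 19 synthetases 14 rose and 2 fell, also over the list alone (camera adjusted p = 6.34e-05; adjusted p = 0.118 with an estimated correlation). Of 15 mRNAs with upstream reading frames 7 rose and 1 fell, 7 and 2 over the list alone (camera adjusted p = 0.0491; adjusted p = 0.171 with an estimated correlation), with Ppp1r15a up 3.85-fold, Slc35a4 down 1.89-fold, and Atf5 (log2 -0.51 ± 0.20 SE, adjusted p = 0.0511), Ppp1r15b and Actb (log2 0.04 and -0.13) not called. Of 26 matrix genes 19 fell and 1 rose, also over the list alone, Col6a3 by 2.79-fold (camera adjusted p = 1.12e-08; adjusted p = 0.0476 with an estimated correlation). Of 10 fibroblast markers 6 fell, with 6 falls and 1 rise over the list alone (camera adjusted p = 0.0108; adjusted p = 0.171 with an estimated correlation). Of 7 IRE1 decay substrates 4 fell and 1 rose, also over the list alone, with a median of -0.38 that turned to 0.15 as deposited (camera adjusted p = 0.0329; adjusted p = 0.282 with an estimated correlation). The list-wide tests of sterol synthesis (3 rose, 8 fell of 19, also over the list alone, with Hmgcs1 down 2.31-fold; camera adjusted p = 0.151) and of oxidative phosphorylation (11 rose, 20 fell of 72, with 11 and 21 over the list alone and Uqcrh down 2.1-fold; camera adjusted p = 0.0655) gave no call. Rab39b, which encodes a GTPase of membrane traffic, rose 15.4-fold, Car6 rose from a dim signal and Edn1 fell to it. In all, 2479 genes rose and 2041 fell (4520 calls). Deposited values put the median change at 0.53, with 5062 rises and 394 falls, and spike-in scaling gave 2217 and 305.

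In the free pool, Hspa5 rose 3.76-fold (log2 1.91 ± 0.09 SE, n = 2 and 3, adjusted p = 2.94e-10), Creld2 12.5-fold and Sel1l 7.1-fold. Atf4 fell 1.32-fold (log2 -0.40 ± 0.11 SE, adjusted p = 0.0108), Eif4b, which encodes an initiation factor, fell 2.24-fold, and Psmb7, a catalytic subunit of the proteasome, 3.75-fold. Ibtk rose 1.7-fold, Eprs 1.38-fold and Ppp1r15b 1.86-fold. Thbs1 fell 10.5-fold, and Edn1 and Bckdha, a subunit of the enzyme that breaks down branched-chain amino acids, fell to a dim signal.

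Of 25 ER chaperones 22 rose in the free pool, 23 over the list alone (camera adjusted p = 2.78e-20; adjusted p = 0.000761 with an estimated correlation). Of 30 ISR genes 26 rose and 1 fell, 26 and 3 over the list alone, with Trib3 up 8.97-fold and Ddit3 8.35-fold (camera adjusted p = 8.38e-20; adjusted p = 0.00528 with an estimated correlation). In ER-associated degradation 11 of 18 rose and 1 fell, 12 and 1 over the list alone, with Herpud1 up 8.8-fold (camera adjusted p = 3.91e-09; adjusted p = 0.00304 with an estimated correlation). Of 15 mRNAs with upstream reading frames 9 rose and 2 fell, also over the list alone (camera adjusted p = 0.00132; adjusted p = 0.0439 with an estimated correlation), with Ppp1r15a up 5.38-fold, Slc35a4 down 1.64-fold, and Atf5 (log2 -0.43 ± 0.20 SE) and Actb (log2 -0.00 ± 0.13 SE) not called. Of 19 synthetases 9 rose and 2 fell, 12 and 3 over the list alone (camera adjusted p = 0.00197; adjusted p = 0.208 with an estimated correlation), and with the 3' spike-in probe sets as scale their median turned to -0.07. Of 72 oxidative phosphorylation genes 36 fell and 4 rose, 39 and 6 over the list alone, including Uqcrh (3.19-fold lower) and Ndufc1 (2.31-fold) (camera adjusted p = 6.1e-07; adjusted p = 0.441 with an estimated correlation). In sterol synthesis 9 of 19 fell, 11 over the list alone, with Hmgcs1 down 2.13-fold and Fdft1 2.06-fold (camera adjusted p = 2.19e-05; adjusted p = 0.0556 with an estimated correlation). Of 26 matrix genes 12 fell and 4 rose, also over the list alone, Dcn by 3.45-fold (camera adjusted p = 0.019; adjusted p = 0.352 with an estimated correlation). Of 10 fibroblast markers 4 fell and 1 rose, 5 and 1 over the list alone (camera adjusted p = 0.0347; adjusted p = 0.236 with an estimated correlation), and of 7 IRE1 decay substrates 5 fell, also over the list alone (camera adjusted p = 0.00274; adjusted p = 0.164 with an estimated correlation). The proteasome list (15 fell, 4 rose of 34, also over the list alone, Psma2 by 1.98-fold) gave no call (camera adjusted p = 0.0612), nor did ER translocation (7 rose, 4 fell of 22, also over the list alone; camera adjusted p = 0.152). Eif2a, which does not encode a subunit of eIF2, fell 2.09-fold, Acot2 rose 11.5-fold, and Car6 rose from a dim signal. In all, 1731 genes rose and 1836 fell (3567 calls), with 517 and 1342 on deposited values, whose median change was -0.09 against 0.02 after centring, and 353 and 241 with spike-in scaling. The pool includes the array with the weak 5' spike-in signal. On that array the mean of the 3' spike-in probe sets was 11.56, against 10.97 to 10.98 on the other free arrays, which moves the scale built on them. The mean of all 12 spike-in probe sets was 10.21 there, against 10.7 to 10.73, which moves that scale as well. The 2 thapsigargin free arrays correlated at 0.955, against 0.974 to 0.976 among control free arrays. The SEs, shared over groups, do not show this wider spread. They can therefore be too small for genes that varied more on the thapsigargin free arrays. Atf5 had an SD of 0.682 log2 units there, against 0.154 on control free arrays. Not every gene varied more there, as Ibtk had SDs of 0.187 and 0.337.

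In unstressed cells, transcripts differed widely in where they lay along the gradient. Cdkn2a, which encodes the tumour suppressors p16 and p19ARF, was 24.9-fold higher in the polysome pool than in the free pool, relative to the median probe set (log2 4.64 ± 0.22 SE, n = 3 and 3, adjusted p = 2.36e-11). Preb, which encodes a factor of ER export, was 12.5-fold higher, the lysosomal protease gene Lgmn 7.44-fold and the histone chaperone gene Asf1b 7.23-fold. Noncoding Neat1 and Dancr were 60-fold and 55.7-fold lower and the ribosomal protein gene Rpl12 21.1-fold (log2 -4.40 ± 0.17 SE). The small open reading frame gene Smim27 was lower, at a dim signal on polysomes. Atf4, Ddit3 and Atf5 were 4.45-, 4.71- and 6.21-fold lower in the polysome pool.

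Of 42 ribosomal protein genes 40 were lower on polysomes and 2 were not called, also over the list alone, with a median of -1.39 relative to the array median and 1.23 as deposited (camera adjusted p = 3.08e-18; adjusted p = 0.209 with an estimated correlation). Rps27, Rpl41 and Rps19 were 7.09-, 3.99- and 3.94-fold lower. Of 19 other 5' TOP mRNAs, which carry a pyrimidine tract that ties their translation to growth signals, 17 were lower and 1 higher, also over the list alone, with a median of -1.2 and of 1.42 as deposited (camera adjusted p = 1.19e-07; adjusted p = 0.236 with an estimated correlation). Pabpc4 was 8.56-fold lower, the elongation factor gene Eef2 4.39-fold and Pabpc1 3.47-fold. Of 316 long noncoding RNAs 217 were lower and 11 higher, at a median of -1.33 against 0.06 for 10872 protein-coding genes.

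Of 34 proteasome genes 29 were higher on polysomes and 2 lower, 30 and 2 over the list alone (camera adjusted p = 1.03e-06; adjusted p = 0.0969 with an estimated correlation). Psmb2 was 3.12-fold higher, and Psmd7 (3.97-fold) and Psmd13 (3.43-fold) turned lower with the mean of all probe sets (log2 -2.05 and -0.29). Of 25 ER chaperones 17 were higher and 2 lower, also over the list alone (camera adjusted p = 0.00173; adjusted p = 0.0771 with an estimated correlation), with Creld2 3.75-fold and Pdia3 3.7-fold higher. Pdia6 was 6.63-fold higher but turned to a log2 of -0.11 with the mean of its probe sets. In ER-associated degradation 13 of 18 were higher and 3 lower, also over the list alone (camera adjusted p = 0.041; adjusted p = 0.15 with an estimated correlation). In sterol synthesis 12 of 19 were higher and 3 lower, also over the list alone, with Fdps at 2.98-fold and Idi1 at 2.85-fold (camera adjusted p = 0.0236; adjusted p = 0.236 with an estimated correlation). Of 20 immediate early genes 10 were lower and 3 higher, also over the list alone, with Zfp36 5.49-fold lower and the list's median at -0.33, or 2.3 as deposited (camera adjusted p = 0.0258; adjusted p = 0.363 with an estimated correlation).

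Several lists split in control cells without a call for the list. Of 30 ISR genes 13 were higher and 6 lower, also over the list alone (camera adjusted p = 0.714), and of 19 synthetases 7 were higher and 8 lower, also over the list alone (camera adjusted p = 0.704), with Hars 5.27-fold higher and Qars, Vars and Eprs 3.84-, 2.94- and 2.45-fold lower. Of 15 mRNAs with upstream reading frames 8 were higher and 5 lower, also over the list alone (camera adjusted p = 0.996, median 0.33), with Ibtk 1.48-fold and Ppp1r15b 1.26-fold higher and Slc35a4 2.25-fold lower. Ppp1r15a (log2 -0.29 ± 0.17 SE) and Hspa5 (log2 0.06 ± 0.08 SE) were not called, and Actb was 1.93-fold lower relative to the median probe set. Of 30 cell cycle genes 16 were higher and 5 lower, also over the list alone (camera adjusted p = 0.062), including Cdc20 (3.55-fold) and the mitotic kinase gene Aurkb (2.9-fold). Of 72 oxidative phosphorylation genes 34 were higher and 23 lower, also over the list alone (camera adjusted p = 0.71), with Cox7c lower at a dim signal on polysomes, and the chemokine gene Cxcl1 was 6.03-fold lower. In all, 4071 genes were higher and 3576 lower (7647 calls). As deposited, the median gene lay 2.65 log2 units higher on polysomes, with 10762 genes higher and 92 lower, so these directions hold relative to the median probe set.

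Under thapsigargin, 11 of 19 tRNA synthetase mRNAs moved toward polysomes and 0 away, while of 25 ER chaperone mRNAs 9 moved away, 1 toward and 15 were not called. These moves are relative to the median probe set of each array. On that scale the median protein-coding gene shifted by -0.109. The polysome shift compares polysome minus free between treated and control cells. A shift away is therefore not a fall on polysomes, as the free pool can change more. Hspa5 rose by a log2 of 1.10 on polysomes and 1.91 in the free pool. Ppp1r15b changed by 0.09 and 0.90. Likewise Psmb7 shifted toward with a fall in the free pool (-1.91) and polysome means of 5.22 in control and 4.96 in treated cells. Its SEs are shared over the gradient groups, so they do not show the wider spread of the thapsigargin free arrays. Atf5 shifted by a log2 of 2.20 ± 0.28 SE (adjusted p = 6.75e-05), Ddit3 by 1.81 ± 0.21 SE, Eprs by 1.75 ± 0.15 SE, Ibtk by 1.51 ± 0.23 SE and Atf4 by 1.49 ± 0.16 SE. Hspa5 shifted by -0.81 ± 0.12 SE (adjusted p = 0.000276), Ppp1r15b by -0.81 ± 0.12 SE and Creld2 by -1.62 ± 0.15 SE. Ppp1r15a (0.19 ± 0.27 SE), Slc35a4 (0.18 ± 0.19 SE) and Actb (-0.22 ± 0.19 SE) were not called. A second probe set of Ddit3 gave -0.27, and the other probe sets of Hspa5 gave -0.48 and 0.14.

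Of 19 synthetases 11 shifted toward polysomes and 8 were not called, 12 toward and 1 away over the list alone (camera adjusted p = 5.42e-08; adjusted p = 0.0439 with an estimated correlation). Besides Eprs they included Qars (log2 1.35), Tars (1.32) and Vars (1.22). Of 30 cell cycle genes 13 shifted toward polysomes, 13 toward and 1 away over the list alone (camera adjusted p = 8.16e-06; adjusted p = 0.0439 with an estimated correlation), among them the helicase subunits Mcm3 (1.29) and Mcm6 (1.16) and the kinesins Kif11 (1.23) and Kif20a (1.13). Of 15 mRNAs with upstream reading frames 5 shifted toward and 3 away, 6 and 4 over the list alone (camera adjusted p = 0.0406; adjusted p = 0.162 with an estimated correlation). Of 30 ISR genes 6 shifted toward, also over the list alone, including Nupr1 (1.25) and the glycine transporter gene Slc6a9 (1.02) (camera adjusted p = 0.0416; adjusted p = 0.408 with an estimated correlation). Of 25 ER chaperones 9 shifted away and 1 toward, also over the list alone (camera adjusted p = 0.0463; adjusted p = 0.209 with an estimated correlation), with Pdia6 at -1.10 and Dnajc10 at -0.95, and the list's median of -0.26 turned to 0.04 as deposited and 0.33 with the 3' spike-in probe sets as scale. The 3' scale leans on thapsigargin free array 3, where the mean of those probe sets was 11.56, against 10.97 to 10.98 on the other free arrays. In ER-associated degradation 4 of 18 shifted away, also over the list alone, with Erlec1 at -1.05, Edem2 at -1.04 and Derl1 at -0.71, with no call for the list (camera adjusted p = 0.312).

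Members of other lists moved both ways. Of 34 proteasome genes 8 shifted away and 3 toward, 9 and 4 over the list alone (camera adjusted p = 0.806), with Psmb7 at 1.65, Psmd1 at 0.65 and Psmd9 at -1.28. Of 72 oxidative phosphorylation genes 12 shifted toward and 11 away, also over the list alone (camera adjusted p = 0.964). Eif2a (1.40) and Eif2b3 (0.92) shifted toward polysomes, and Map1lc3b, which encodes an autophagosome protein, away (-0.79). The noncoding Snhg12 (2.32) shifted toward and Scara3 (-2.82) away. Bckdha also shifted toward, and Tmem119, Lmcd1 and Fgf5 away, each with a dim signal in the free or polysome pool of treated cells. In matrix genes 2 of 26 shifted toward and 3 away, also over the list alone (camera adjusted p = 0.571), in IRE1 decay substrates 2 of 7 away, with 1 toward and 3 away over the list alone (camera adjusted p = 0.25), and in sterol synthesis 3 of 19 toward, 2 over the list alone (camera adjusted p = 0.239). Of 42 ribosomal protein genes 1 shifted away, 0 over the list alone (camera adjusted p = 0.0646).

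In all, 1067 genes shifted toward polysomes and 1609 away (2676 calls; 4092 genes at an unadjusted p under 0.05). The median shift was -0.11 after centring and 0.19 as deposited, where 1027 genes shifted toward and 114 away. Scaling to the spike-ins left 22 calls, 18 toward and 4 away. That count leans on thapsigargin free array 3. The mean of the 12 spike-in probe sets was 10.21 there, against 10.7 to 10.73 on the other free arrays. Leaving out control culture 1 or 2 gave 1556 and 1533 calls. Without the free array with the weak 5' signal, 13 synthetases and 15 cell cycle genes shifted toward and 1 cell cycle gene away, and 6 chaperones shifted away and 1 toward. Of 821 genes higher in total RNA, 154 shifted toward polysomes and 81 away, against 77.73 and 117.2 for independent lists. Of 880 lower genes 260 shifted away and 39 toward, against 125.6 and 83.31.

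**Figure D2:**
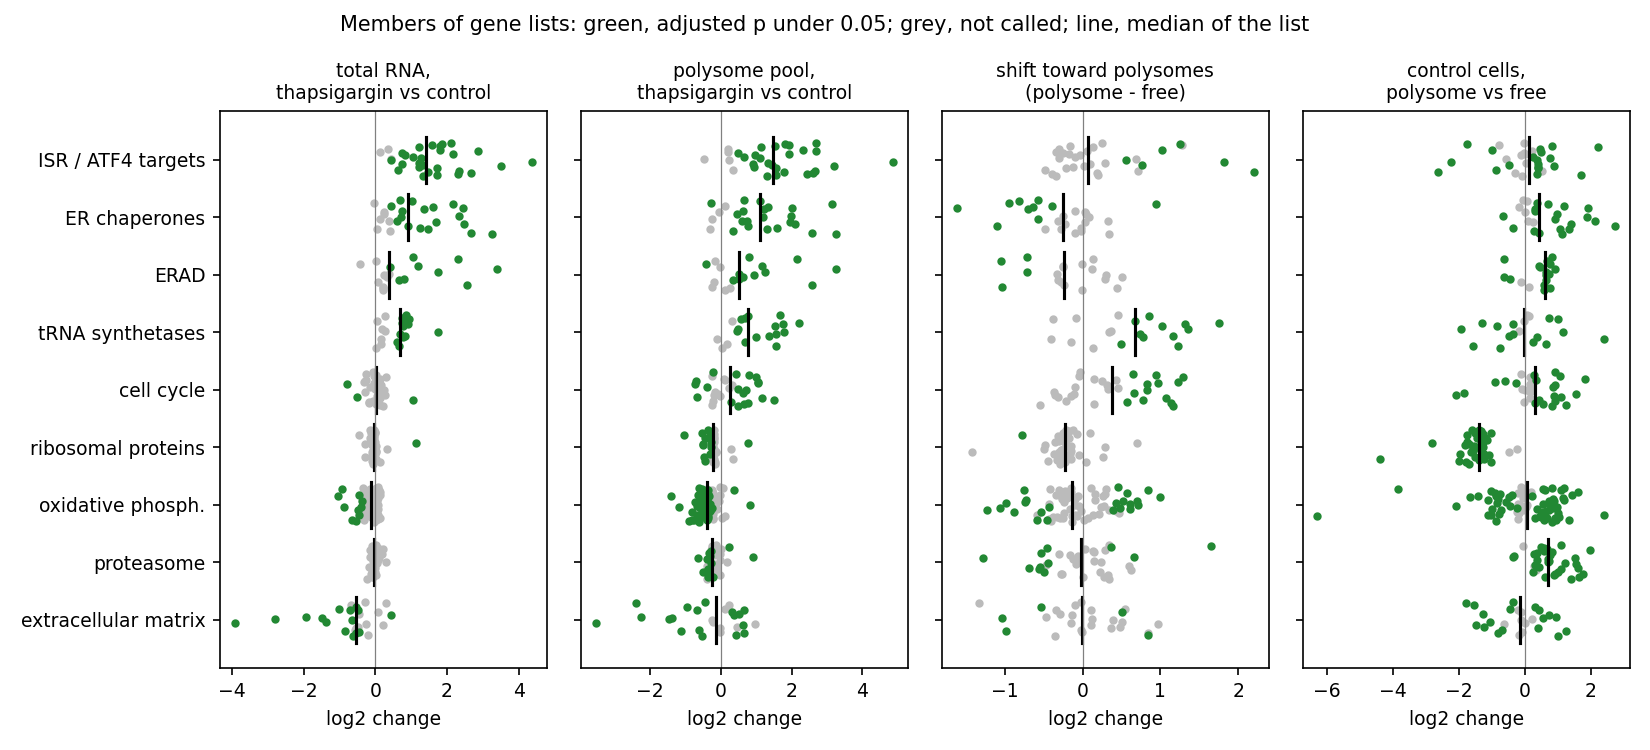
Log2 change (horizontal axes) of every measured member of 9 gene lists (rows) in total RNA and the polysome pool, thapsigargin against control, in the polysome shift, and between the polysome and free pools of control cells; green points have an adjusted p under 0.05, grey points do not, and black lines are list medians. In the shift, the synthetase median lies at 0.68 and the ER chaperone median at -0.26, the latter turning above 0 without centring.

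The share of a transcript's gradient signal found in the polysome pool, on deposited values, gave the same genes in percent. Ibtk went from 33.5% ± 3 (SD, n = 3 control cultures) to 67.1% ± 5.5 (n = 2 thapsigargin cultures) and Eprs from 40.9% ± 0.35 to 69.2% ± 0.21. Atf5 went from 18.1% ± 3.2 to 47.4% ± 3.7, Atf4 from 29.4% ± 3.5 to 46.5% ± 3.3 and Ddit3 from 20.4% ± 4.3 to 37.7% ± 4.7. Ppp1r15a went from 37% ± 2.6 to 42.7% ± 2.1. Hspa5 went from 63.8% ± 3.3 to 52.4% ± 5.5 and Ppp1r15b from 60.5% ± 2.3 to 54.9% ± 3, while the median gene went from 54.9% ± 1.8 to 49.6% ± 3.1. In these 8 of 10 genes the cultures of the 2 groups did not overlap. Chance alone gives this for 20% of genes, but the median of all genes did not overlap either. The share over all genes was not counted, so the 8 of 10 have no background to be set against. Ppp1r15b moved by -5.58 points, against -5.35 for the median gene. Slc35a4 (26.4% ± 2 and 27.6% ± 0.9) and Actb (51.9% ± 4.6 and 47.1% ± 3.9) had overlapping cultures. A second probe set of Ddit3 gave 8.84% ± 6.2 and 7.67% ± 0.65, and another of Hspa5 57.3% ± 6.1 and 59.1% ± 3.8, both with overlapping cultures, so the moves of these genes rest on the probe sets used. The remaining probe set of Hspa5 fell like the one used, from 66.6% ± 1.6 to 55.8% ± 4.1, without overlap. The percentages also depend on the scaling. After centring, Ibtk went from 22% ± 3.5 to 55.6% ± 2.9, Eprs from 19.7% ± 0.58 to 46.4% ± 2.8, Atf5 from 7.91% ± 1.2 to 28.6% ± 2.6, Atf4 from 12.4% ± 1.3 to 26.7% ± 0.35 and Ddit3 from 9.46% ± 1.6 to 24% ± 0.3. Hspa5 then went from 38.5% ± 1.8 to 28.4% ± 2.6, and the median gene from 32.8% ± 0.39 to 31.6% ± 0.58. No p is given, as 3 against 2 cultures cannot reach an exact p below 0.1.

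**Figure D3:**
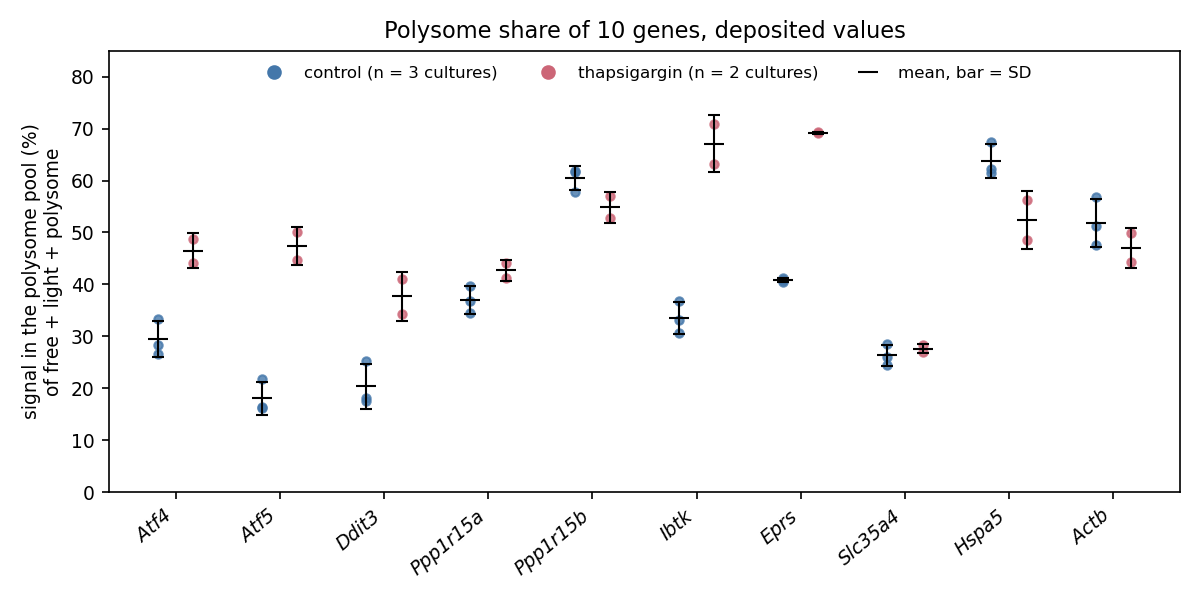
Share of gradient signal in the polysome pool (vertical axis, percent of free plus light plus polysome) for 10 genes (horizontal axis); points are cultures, blue for control (n = 3) and red for thapsigargin (n = 2), dashes are means and bars SDs. Ibtk, Eprs, Atf5, Atf4 and, for the probe set shown, Ddit3 lie higher under thapsigargin in both cultures than in any control culture.

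The change on polysomes was then set against the change in total RNA. Eprs rose on polysomes beyond its rise in total RNA by a log2 of 1.48 ± 0.19 SE (adjusted p = 0.000317), as did Lars (0.89 ± 0.13), Vars (0.89 ± 0.24) and Tars (0.85 ± 0.12). Pola1, a subunit of the polymerase that primes DNA replication, was higher (1.60 ± 0.29), as was the condensin gene Ncapg (1.54 ± 0.32). The genes Egfl8, Fgf5 and Eln, which encodes elastin, were lower, each with a dim signal on polysomes of treated cells. The dynein heavy chain gene Dync1h1 (-1.15) was also lower in this contrast. Its polysome mean was nonetheless higher in treated than in control cells (0.18 against -0.20). Ibtk (0.64 ± 0.26 SE, adjusted p = 0.173), Ddit3 (0.50 ± 0.20, adjusted p = 0.175) and Atf4 (0.47 ± 0.17, adjusted p = 0.113) were not called.

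Of 19 synthetases 6 were higher beyond total RNA and 13 not called, 8 higher over the list alone (camera adjusted p = 3.51e-08; adjusted p = 0.0875 with an estimated correlation). Of 30 cell cycle genes 7 were higher, 10 higher and 1 lower over the list alone (camera adjusted p = 2.45e-06; adjusted p = 0.0322 with an estimated correlation), including Kif11 (1.37), Top2a (1.08), Mcm4 (1.04) and Kif20a (0.92). Of 26 matrix genes 7 were higher and 1 lower, 10 and 1 over the list alone (camera adjusted p = 7.32e-07; adjusted p = 0.178 with an estimated correlation), with Col1a1 at 1.35, Col3a1 at 1.34 and the laminin gene Lamc1 at 1.20. Of the 15 mRNAs with upstream reading frames, Eprs was the 1 called, also over the list alone (camera adjusted p = 0.0674), and Atf5 (0.31), Hspa5 (0.06), Slc35a4 (0.02), Actb (-0.04), Ppp1r15b (-0.06) and Ppp1r15a (-0.06) were not called. Of 72 oxidative phosphorylation genes Ndufs1 was higher (0.75) and 71 were not called, also over the list alone (list lower by camera, adjusted p = 0.000353; adjusted p = 0.68 with an estimated correlation). Of 34 proteasome genes Psmd1 was higher (1.04) and 33 were not called (list lower by camera, adjusted p = 0.0416; adjusted p = 0.598 with an estimated correlation), with 1 higher and 2 lower over the list alone. Of 42 ribosomal protein genes 42 were not called, also over the list alone (list lower by camera, adjusted p = 0.0118; adjusted p = 0.795 with an estimated correlation). The medians of the proteasome and ribosomal protein lists, -0.22 and -0.19, turned to 0.05 and 0.07 as deposited, and relative to all genes to 0.03 and 0.07 with quantile normalization. Of 30 ISR genes and of 25 ER chaperones 1 each was higher, also over the list alone (camera adjusted p = 0.609 and 0.931). Outside the lists, Top2b, which encodes another topoisomerase, was higher by 1.45. The change beyond total RNA also rose with gene span, the length of genome a gene covers (rank correlation 0.287 over protein-coding genes). These list tests were not adjusted for span, so a part of it in their calls cannot be told apart.

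In all, 298 genes were higher and 168 lower beyond total RNA (466 calls; 2285 at an unadjusted p under 0.05), with 213 and 2 on deposited values, whose median change was 0.12 against -0.15 after centring. Leaving out the arrays of 1 replicate number moved the count to 45, 39 or 91 for control 1, 2 or 3 and to 1418 or 147 for thapsigargin 1 (total RNA alone) or 3, and 836 genes were called without thapsigargin free array 3. Without that array and total RNA array 2 there were 1062 calls, with 8 synthetases and 12 cell cycle genes higher, and 12 matrix genes higher and 1 lower. Of 15 mRNAs with upstream reading frames 4 were then higher. Of ISR genes 4 were higher and 1 lower, and of ER chaperones 1 was higher and 1 lower. The free array is not in the groups compared here.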

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

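The tests of the array with weak 5' signal and of the lists were chosen after the results were seen; the counts of other splits of the samples were planned before.

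By the interaction terms in limma, the polysome minus free difference of 2676 genes differed between thapsigargin and control cells, and for 466 genes the change on polysomes differed from the change in total RNA. Each split of 6 arrays into 3 and 3 was also fitted where groups had 3 arrays. Of the 10 splits of the total RNA arrays, 1 gave as many genes as the real 1701, the real one itself, and the highest other gave 0. Of the 10 splits of the control polysome and free arrays, 1 gave as many as the real 7647, again the real one, and the highest other gave 0. In both cases 10 splits are too few for a share under 0.05.

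Control probe sets that no comparison used set 2 arrays apart. On thapsigargin free array 3, the 3' signal exceeded the 5' signal by a log2 of 3.62 for the spike-in dap (at most 0.44 on control free arrays), 3.64 for thr (1.31), 2.47 for phe (0.77), 1.47 for lys (-0.12) and 2 for actin (0.71). On the 6 total RNA arrays the spike-ins behaved much alike, with 2.36 to 3.57 for dap and 2.24 to 3.23 for thr, but actin at 0.24 to 0.60. Thapsigargin total RNA array 2 had an 18S ribosomal RNA signal 2.48 log2 units over the array median, against at most -0.61 in control total RNA.

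The tables argue against another pool, total RNA or a control culture on thapsigargin free array 3. A different thapsigargin free sample could not be told apart this way. Its highest correlation with an array of another pool or of total RNA was 0.911, below its lowest correlation with a free array, 0.937. Its median for the stress response list lay 1.23 log2 units above the control free mean, where thapsigargin free array 2 lay 0.98 above, which argues against a control culture. Why its spike-ins resemble those of the total RNA arrays stays open, as does a loss of 5' signal in RNA handling or labelling, and neither was tested, and no biological explanation was tested.

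A pattern in the polysome shift was the gap between the synthetase list (median log2 0.68, 11 of 19 genes toward) and the ER chaperone list (-0.26, but 0.04 as deposited, 9 of 25 away and 1 toward), a difference of 0.94. Without thapsigargin free array 3 the difference was 1.04, with the trend over gene span removed 0.89, and with the mean of all probe sets of each gene 0.90, which argues against each of these as the whole cause. The difference between lists does not depend on the scaling of whole arrays. Thapsigargin may change the ribosome load of these lists unequally, a hypothesis found and tested on the same 5 gradients. Other technical causes, and a change in which transcript forms are present, stay open.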

How the results depend on the processing

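Scaling to the 3' spike-in probe sets, leaving out thapsigargin free array 3 alone outside the free pool and, for the change beyond total RNA, leaving out total RNA array 2 alone or with it were chosen after seeing the data. All others were planned. Unless stated, the cause of a difference was not tested.

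The text names 271 gene results, which gave 4620 of 4878 values on the same side of the threshold and in the same direction. Of the others 228 lost a call, 27 gained a call and 3 reversed. With deposited and spike-in scaled values, named genes were judged relative to the median change of all genes. These settings therefore could not show reversals from the scale of whole arrays. In control polysome against free, that median was 2.65 as deposited. Of the 246 called, 164 kept their call and direction in every alternative run, among them 41 of 53 in total RNA and 38 of 48 on polysomes, but 9 of 37 in the polysome shift and 4 of 20 beyond total RNA. The reversals came with the mean of all probe sets in control polysome against free, where Pdia6 gave -0.11, Psmd7 -2.05 and Psmd13 -0.29, so probe sets of these genes differ.

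On deposited values there were 2609 calls on polysomes (main 4613), 1859 in the free pool (3567), 1141 in the shift (2676) and 215 beyond total RNA (466). Scaled to the 12 spike-in probe sets there were 1252 on polysomes, 2522 in the light pool (4520), 594 in the free pool and 22 in the shift. Scaled to the 4 probe sets for their 3' ends, 2382 rose and 1259 fell on polysomes, 5503 and 562 in the light pool, 401 and 4540 in the free pool, and 3837 and 157 in the shift. In control polysome against free, these gave 10611 higher and 131 lower, and all 12 spike-in probe sets 10562 and 92. The mean of the 4 was 11.56 on thapsigargin free array 3, against 10.97 to 10.98 on the other free arrays. The mean of the 12 was 10.21 there, against 10.7 to 10.73. The counts of both scales for the free pool and the shift therefore lean on that array. The other gradient counts share that array's spread through the common model. Quantile normalization stayed within 1.5 times every count.

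Array weights gave 6653 calls in total RNA, 1087 in the free pool, 1395 in the shift and 4091 beyond total RNA. Total RNA fitted in the model of all 21 arrays gave 2860. A log2 change of at least 1, which is stricter by construction, left 555 calls in total RNA, 986 on polysomes, 928 in the light pool, 647 in the free pool, 3133 in control polysome against free, 694 in the shift and 118 beyond total RNA. For the change beyond total RNA, the mean of all probe sets gave 302, the polysome and total RNA arrays alone 267, and a term for the mark in the array names 264. The mark stood on all gradient arrays of control cultures 1 and 2 and on no thapsigargin array. It is thus partly confounded with treatment. The replicate block, a term per culture, gave 1119 beyond total RNA, and paired terms gave between 2217 in total RNA and 7760 in control polysome against free for the others. Deviations of control and thapsigargin total RNA of the same number correlated at 0.0749, 0.119 and 0.227. Each of the 6 samples correlated best with its own number, a hint from the data and not the design. As 1 of the 3 pairs was under 0.1, the numbers were not taken to pair the treatments.

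Leaving out 1 replicate gave 812 to 3327 calls in total RNA, 3024 to 4292 on polysomes, 3144 to 3991 in the light pool, 3111 to 4667 in the free pool, 6665 to 6697 in control polysome against free, 1533 to 3407 in the shift and 39 to 1418 beyond total RNA. The ends of the wide ranges came without control 2 and thapsigargin 2 in total RNA and the shift, and without control 2 and thapsigargin 1 beyond total RNA. Where 1 array of a group was left, it was taken to vary like the other groups. Without thapsigargin free array 3 there were 5626 calls on polysomes and 836 beyond total RNA.

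Dim probe sets limit what can be seen. Without the filter, 18193 genes were tested, and 1335 rose and 647 fell in total RNA, 2479 and 1432 on polysomes, 3608 and 1090 in the light pool, 6781 and 1953 in control polysome against free, 1234 and 721 in the shift, and 286 and 53 beyond total RNA. The calls for gene lists went from 61 to 17 with an estimated correlation and to 95 with fry, which asks another question. The polysome shares of 8 of 10 genes did not overlap between groups on deposited values, against 10 after centring, 9 with spike-in scaling and 7 with the 3' spike-in probe sets, where Ppp1r15b, Slc35a4, Actb and the median of all genes overlapped. Chance alone gives 20% of genes. On deposited values, after centring and with spike-in scaling the median of all genes did not overlap either, so that share is no yardstick there. An offset on the linear scale was not run, since the values were already log2.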

Other observations

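The tests of the pattern over gene span were all chosen after the result was seen; the counts of gene lists were planned.

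Several lists outside the report's comparisons changed in single members without a call for the list. Of 15 NF-kappaB targets, 3 rose and 5 fell in total RNA, 5 and 7 over the list alone (camera adjusted p = 0.344). The chemokine gene Cxcl10 rose 2.78-fold, and the adhesion molecule gene Vcam1, the chemokine gene Ccl2 and the inhibitor gene Tnfaip3 fell 3.87-, 3.47- and 2.91-fold. Of 20 immediate early genes 3 rose and 2 fell, 4 and 2 over the list alone (camera adjusted p = 0.435), with Klf4 up 2.58-fold, Myc up 1.73-fold, Egr3 down 2.24-fold and the phosphatase gene Dusp1 down 2.08-fold. Of 15 apoptosis and p53 response genes 3 rose and 1 fell, 3 and 2 over the list alone (camera adjusted p = 0.707). The p53 targets Bbc3 and Cdkn1a rose 1.73- and 1.67-fold, and Bcl2l11, which encodes the cell death protein BIM, fell 1.91-fold. On polysomes 1 rose and 9 fell, 2 and 9 over the list alone (camera adjusted p = 0.146), with Casp12 down 2.88-fold, Bcl2l11 2.53-fold and Bak1 1.87-fold. In total RNA without thapsigargin array 2, 3 NF-kappaB targets rose and 7 fell. For immediate early genes these counts were 4 and 6, and for the apoptosis list 3 and 4.

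Of 18 autophagy genes 4 rose in total RNA, 4 with 1 fall over the list alone (camera adjusted p = 0.317), the cargo receptor gene Sqstm1 by 2.44-fold. Without thapsigargin total RNA array 2, 5 rose and 4 fell. On polysomes 2 rose and 7 fell, also over the list alone (camera adjusted p = 0.996), with Sqstm1 up 2.6-fold, Nbr1 up 1.95-fold and Map1lc3b down 1.65-fold. In the shift 2 moved toward and 7 away, 3 and 8 over the list alone (camera adjusted p = 0.221), Vmp1 (log2 0.94) and Nbr1 (0.93) toward. The list of the eIF2 machinery held 13 genes of eIF2 kinases, eIF2 and its exchange factor, with Eif2a and Nck1, which encode none of these. In total RNA 2 of them rose and 1 fell, also over the list alone (camera adjusted p = 0.574), Eif2ak3, which encodes the ER stress kinase PERK, by 2.05-fold. Of 5 macrophage markers 5 were not called, also over the list alone (camera adjusted p = 0.679). Of 5 neural markers the tubulin gene Tubb3 rose 3.17-fold, with 2 falls over the list alone (camera adjusted p = 0.957). Of 4 epithelial markers Krt19 fell 1.82-fold, and 3 muscle markers and 1 fat marker were not called, with the same counts over each list alone. The 1 mitochondrially encoded gene, ND5, was not called over all genes and fell when adjusted over the list alone. These 4 lists were too short for a list test, and 0 endothelial markers were measured.

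Genes called higher on polysomes beyond total RNA spanned more of the genome than others, by the lengths in the GRCm38.p6 gene table. Their median span was 59.6 kb (293 of 298 genes, the protein-coding ones with a length), against 18.2 kb for those called lower (164 of 168) and 24 kb for all 10872 protein-coding genes with a length. Over these the rank correlation of span with the change beyond total RNA was 0.287, against -0.00971 with the change in total RNA, 0.197 on polysomes, -0.0139 in the light pool and 0.0514 in the free pool. In 5 groups of genes of equal number ranked by span, with medians of 4.6, 12.5, 24, 45.5 and 118 kb, the median change beyond total RNA was -0.25, -0.23, -0.15, -0.06 and 0.04. Genes are not independent replicates, so no p is given.

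Low RNA quality on thapsigargin total RNA array 2 is argued against as the whole cause, as the correlation was 0.208 without that array, though it fell. Brightness of the probe sets is argued against too, with 0.274 after its trend was removed. Whether transcripts of longer genes lie more often in the pool of 4 or more ribosomes under stress stays open. Polysome minus light signal against the control mean correlated with span at 0.179 and 0.184 in the 2 thapsigargin cultures, but it reuses the polysome arrays that gave the pattern, so it decides nothing. Span includes introns, and lengths of transcripts were not used here.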
